A study of Mus musculus with 12 samples.

How the data were processed

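Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, so that reads pile up where chromatin is accessible. Per the labels, each library came from the dentate gyrus of 1 C57BL/6 mouse aged 8 weeks, taken by microdissection. The dentate gyrus is the part of the hippocampal formation that holds the granule neurons. The 12 libraries fall into 3 groups named E0, E1 and E4 with 4 replicates each, taken from the sample titles. The labels do not define the group names. From what is known of the published study, and not from the labels, E0 stands for mice before, E1 for mice 1 h after and E4 for mice 4 h after electroconvulsive stimulation. The comparisons rest on the group names alone.

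One list of peaks per library was used, each peak with a chromosome, a start, an end, a name and a score, as deposited. Per the file contents, peak names carry the prefix of the MACS peak caller, and peaks within a list never overlapped. The score per peak is the authors' own value as deposited. Its scale is not given in the sources used here. The lowest score in a list was 50.0 or 50.01, so the score served only to rank or filter peaks within a list. Reads were aligned with Bowtie2 to mm9, per the submitters' processing notes. The caller's version, its control and threshold, the shift of reads for the transposase's binding footprint, the handling of duplicate and mitochondrial reads and any blacklist of regions are not given in the sources used here. A missing shift would move peak edges by a few bases and a lenient duplicate filter would lengthen the lists of libraries with many copies, and neither can be checked in a peak list.

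The lists give no read counts, so the depth of each library is unknown. List length rises with depth as well as with accessibility, and no interval for sampling error can be given for a peak. Each peak is a yes or no call: a region without a peak in a library was not called there, which does not show that it was closed.

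Coordinates are those of the deposited lists, in mm9, written from 1. Peaks on chromosome 1 reached position 197105523, beyond the last gene end of 195291439 in the GRCm38 gene table that was given. That table is of another build, so no region was assigned to a gene, exon, intron or promoter, and no sequence was read. For this reason the tests of promoters, gene lists and sequence motifs that had been laid down were not run.

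Peaks on chromosomes 1 to 19 and X from all 12 lists were merged wherever they shared at least 1 bp. The result was checked against bedtools 2.31.1, which gave the same 170710 regions. A region counted as present in a library if at least 1 bp of a peak lay in it. A wide peak in 1 library, also of a group outside the comparison, can thus join separate peaks of other libraries into 1 region. Peaks on chromosome Y were left out, 9 to 43 per library.

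Comparisons were made of E1 with E0, E4 with E0 and E4 with E1. The number of peaks, the length covered, the median width and the median score per library were compared by an exact two-sided permutation test of the difference in means over all 70 assignments of 8 libraries. The smallest p this can give is 0.0286. Values were adjusted by the Benjamini-Hochberg method over the 12 tests. A region was called gained when it had a peak in 4 of 4 libraries of the first group and 0 of 4 of the second, and lost in the opposite case. Fisher's exact test gives such a region p = 0.0286, the smallest possible for 4 against 4, so no single region can pass an adjustment over all regions, and the number of such regions was tested instead. It was compared with 1000 randomised tables of presence that keep the number of regions of each library and the number of libraries of each region, which holds list length constant. The permutation p from these tables is one-sided, with 0.000999 as its smallest value. Each region is dealt out independently in the tables, so this p treats regions and not mice as the units. Some regroupings of the libraries that mix the groups also exceeded their tables. This p alone therefore does not test the group label. Gained and lost regions were also set against the other regions found in 4 of the 8 libraries, those that could have been gained or lost. Similarity of peak sets was measured by the Jaccard index, the shared bp over the union bp of a pair of libraries, and tested one-sided over all 5775 regroupings of the 12 libraries into 3 groups of 4, in place of the random draws first laid down.

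Regions were named by a rule: in each comparison the 10 gained and the 10 lost regions with the highest mean percentile of the score within the lists that hold them. This rule, the groups, the tests above and most alternatives were set before the data were examined. The tests of clustering, of 1 Mb windows, of chromosomes and of overlap between lists of regions were added later. Clustering was measured as the share of regions whose nearest other region of the same list lay within 50 kb. It was compared with 1000 random draws of as many regions from those found in 4 of the 8 libraries, with Benjamini-Hochberg adjustment over the 6 lists. Windows with at least 5 regions found in 4 of the 8 libraries, and chromosomes, were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. These tests treat regions as independent.

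Alternatives were lists cut to equal length by score, peaks above the median score of each list, a score minimum common to all lists, autosomes only, presence only where peaks cover at least 50% of a region, merging of peaks up to 100 bp apart, bins of 500 bp, at least 3 of 4 libraries against 0 of 4, a replicate block, and leaving out each library in turn. They used 100 randomised tables each, with 0.00990 as the smallest p. For named regions the cut to equal length is a weak check. It keeps the highest scores, by which the regions were named, and cannot add a peak to the other group. The counting of gained regions was tested on simulated data. In a table randomised from the E1 and E0 libraries (132574 regions), setting 200 regions to gained put the number 141 above expectation (permutation p = 0.0099). The unchanged table gave permutation p = 0.941. For E4 with E0 (131043 regions) the 200 regions put the number 197 above expectation, and for E4 with E1 (140818 regions) 199. Such tables come from the same randomisation as the expectation and hold no likeness between libraries. They check the counting, and not how often real lists would give a small p without a group effect. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.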

Results

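Accessible regions of the dentate gyrus were mapped in 12 mice, 4 in each of the groups E0, E1 and E4, to ask how chromatin accessibility changes when neurons are activated. The deposited lists held 61480, 77155, 36891 and 45048 peaks for E0 replicates 1 to 4. E1 replicates 1 to 4 had 84798, 83053, 70512 and 64173 peaks, and E4 replicates 1 to 4 had 104155, 34872, 24448 and 31763. On chromosomes 1 to 19 and X, the mean was 55115 ± 17892 peaks (SD, n = 4) in E0, 75613 ± 9944 in E1 and 48788 ± 37147 in E4. Peaks covered 25.3 ± 12.4 Mb in E0, 33.5 ± 10.3 Mb in E1 and 22.5 ± 24.8 Mb in E4 (SD, n = 4). The differences in peak number were smaller than the exact permutation test could separate from the spread between mice. E1 had 1.37 times as many peaks as E0 (exact p = 0.114, adjusted p = 0.873), E4 had 0.885 times as many as E0 (exact p = 0.771, adjusted p = 0.873) and E4 had 0.645 times as many as E1 (exact p = 0.20, adjusted p = 0.873). Leaving out E0 replicate 2 brought E1 minus E0 to 27837 peaks (exact p = 0.0286) and turned E4 minus E0 to 1012, as leaving out E4 replicate 3 did, to 1794. Without E4 replicate 1, E4 minus E1 was -45270 peaks (exact p = 0.0286).

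**Figure D1:**
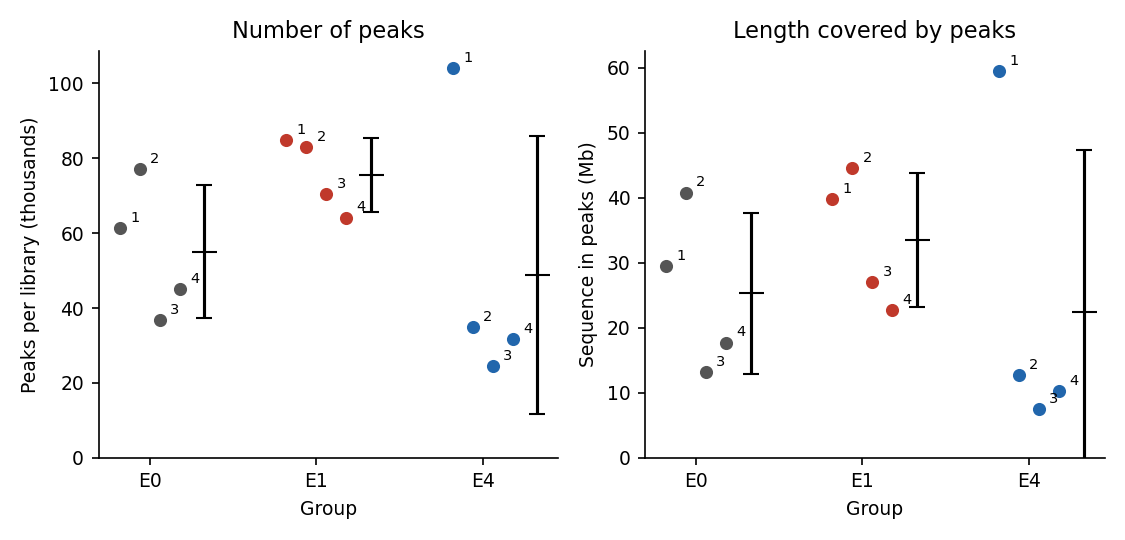
Peaks per library (left, 1000 peaks) and sequence covered by peaks (right, Mb) on chromosomes 1 to 19 and X for each group, with 1 numbered point per replicate and the mean ± SD (n = 4) beside the points (the E4 bar at right is cut at 0). E4 replicate 1 had 104120 peaks, and the other E4 lists had 24426 to 34863.

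The 12 lists merged into 170710 regions with a median width of 399 bp, the widest being 9077 bp. Of these, 9037 regions (5.29%) had a peak in all 12 libraries and 59971 (35.1%) in a single library. On average, peak sets of the same group shared more sequence than peak sets of different groups. This held for E0 and E1 but not for E4 when all E4 pairs were averaged. The mean Jaccard index was 0.344 within groups and 0.293 between groups, a difference of 0.0502 (exact permutation test over 5775 regroupings, one-sided, p = 0.0381). It was 0.427 ± 0.0671 among E1 libraries (SD, 6 pairs), 0.377 ± 0.0751 among E0 libraries and 0.227 ± 0.0925 among E4 libraries. Between groups it was 0.334 for E1 with E0, 0.274 for E4 with E0 and 0.273 for E4 with E1, both above the mean within E4. The highest index of any pair was 0.552, for E1 replicates 1 and 2, so no list repeated another. The difference lost its call (exact permutation p from 0.0608 to 0.113) when E0 replicate 1, 3 or 4 or any single E1 library was left out, with values from 0.0318 to 0.0474, and it was 0.104 without E4 replicate 1.

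The comparison of E1 with E0 asks which regions gain or lose accessibility in the E1 mice. At E1, 5579 regions had a peak in all 4 E1 libraries and in no E0 library, and 310 regions had a peak in all 4 E0 libraries and in no E1 library. Gained regions were 38.4% of the 14525 regions found in 4 of these 8 libraries, and lost regions were 2.13%. The median score of gained regions lay at percentile 59.4 of the E1 lists, against percentile 36.9 for the other regions found in 4 of the 8 libraries in the lists that hold them. Their median width was 551 bp, against 504 bp. Lost regions had a median percentile of 47.8 in the E0 lists, against 44.8, and a median width of 531.5 bp, against 524 bp.

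The region with the highest mean percentile among those gained at E1 lay on chromosome 1 from 40415429 to 40416355 (mm9, 927 bp). It had scores of 498 to 750.2 (SD 113, n = 4) in the E1 lists, no peak in E0 and a peak in 4 of 4 E4 libraries. The next lay on chromosome 10 from 13495193 to 13496509, with a score of 564 ± 81.1 (SD, n = 4) and a peak in 3 of 4 E4 libraries. A region on chromosome 12 from 54854269 to 54854911 scored 533 ± 104 (SD, n = 4) and was present in 2 E4 libraries. On chromosome 11, the region from 12601524 to 12602484 scored 537 ± 98.0 (SD, n = 4) and was present in 4 E4 libraries. The region on chromosome 18 from 12769458 to 12770505 scored 504 ± 88.2 (SD, n = 4) and was also present in 4 E4 libraries. The other five of the 10 lay on chromosome 10 from 17796619 to 17797356 and from 46017953 to 46018688, on chromosome 8 from 91962689 to 91963724, on chromosome 3 from 120828696 to 120830000 and on chromosome 11 from 86653393 to 86654500. Their mean scores ran from 437 to 499 and each had a peak in 2 to 4 of the E4 libraries. All 10 kept 4 of 4 against 0 of 4 with lists of equal length, an outcome close to fixed by their choice for high scores. When peaks had to cover at least 50% of the region, 6 of the 10 did so.

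Among regions lost at E1, the one with the highest mean percentile lay on chromosome 4 from 51691875 to 51692479. It scored 222 ± 37.3 (SD, n = 4) in the E0 lists, had no peak in E1 and had a peak in 2 E4 libraries. A region on chromosome 2 from 80434333 to 80435230 scored 236 ± 85.4 (SD, n = 4) and was present in 3 E4 libraries. On chromosome 14 there were 2 such regions, from 114640567 to 114641176 with a score of 234 ± 99.3 (SD, n = 4) and from 10706738 to 10707288 with a score of 212 ± 91.3 (SD, n = 4), each present in 2 E4 libraries. The other six lay on chromosome 3 from 101493897 to 101494571 and from 37189741 to 37190417, on chromosome 6 from 107269624 to 107270186, on chromosome 4 from 98301818 to 98302905, on chromosome 16 from 96450455 to 96451292 and on chromosome 2 from 118454913 to 118455483. Their mean scores ran from 180.0 to 215, each with a peak in 1 or 2 E4 libraries. All 10 were kept with lists of equal length and 4 of the 10 when peaks had to cover at least 50% of the region.

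Regions gained at E1 lay closer together than other regions. Of the 5579, 31.5% had another gained region within 50 kb, against 27.3 ± 0.695% (SD of 1000 draws) for as many regions drawn from those found in 4 of the 8 libraries (permutation p = 0.000999, the smallest the draws can give, adjusted p = 0.00599 over 6 lists). These shares were 16.2% and 11.5 ± 0.892% with lists of equal length (SD of 1000 draws, permutation test, adjusted p = 0.00599). None of the other five lists passed with lists as deposited, where regions lost at E4 from E0 came nearest (4.03% against 1.46%, permutation p = 0.0320, adjusted p = 0.0959). Equal list length let regions gained at E4 from E0 (6.45% against 2.72%, permutation test, adjusted p = 0.00599) and lost at E4 from E0 (6.77% against 3.64%, adjusted p = 0.00999) pass as well, the former having lain below its draws with lists as deposited (0.862% against 1.38%). Of 1470 windows of 1 Mb, 99 had an unadjusted Fisher's exact p under 0.05 and a single window passed the adjustment. It was chromosome 3 from 136000001 to 137000000, with 16 gained regions and 1 other region found in 4 of the 8 libraries (Fisher's exact test, adjusted p = 0.00354). The 16 ran from 136067284 to 136906688, and 8 of them lay between 136396089 and 136521279. With lists of equal length within the comparison the window held 9 gained and 3 other regions (Fisher's exact p = 0.0129, adjusted p = 0.626), so its call was lost. None of the 671 windows tested then passed the adjustment by Fisher's exact test (lowest adjusted p = 0.0859), and 29 had an unadjusted p under 0.05.

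**Figure D2:**
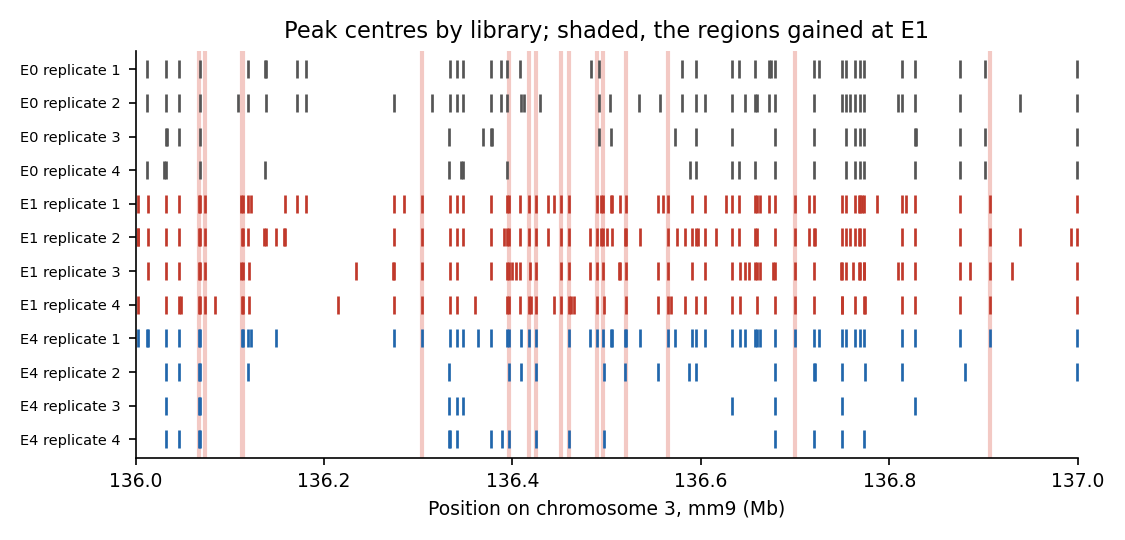
Map of chromosome 3 from 136000001 to 137000000 (mm9), with position in Mb on the horizontal axis, 1 line of ticks per library marking peak centres, and shading at the centres of the 16 regions gained at E1. Each E1 library has a peak in each of the 16 regions and no E0 library has one, the E0 ticks beside the shading being centres of neighbouring peaks. The region from 136495628 to 136497245 is not 1 site shared by the E1 libraries. There a wide peak of E4 replicate 1 joins E1 peaks, and those of replicates 1 and 3, of replicate 2 and of replicate 4 lie apart.

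The number gained at E1 was 7.65 times that expected from list length and region frequency. Randomised tables gave 730 ± 26.6 gained regions (SD of 1000 tables, 646 to 810) and 17.4 ± 4.26 lost regions (5 to 29), and none reached the observed numbers (permutation p = 0.000999 for both, the smallest 1000 tables can give). The same 8 libraries regrouped as replicates 1 and 2 against 3 and 4 also exceeded their tables (1349 regions in both directions, 891 expected). The p therefore does not measure the spread between mice. E1 lists were longer than E0 lists on average, and with every list cut to its 24426 highest scores the split was 2068 gained and 840 lost, against 81.2 and 69.9 expected. With lists cut to 36861 peaks, the shortest among these 8, it was 3004 gained and 1023 lost. Leaving out a library relaxes the criterion to 3 libraries in its group, and moved the gained number by over 1.5 times without E1 replicate 4 (8469), and the lost number without E0 replicate 3 (950), E0 replicate 4 (683), E1 replicate 1 (522) or E1 replicate 2 (492). The ratio to expectation fell by over 1.5 times for gained regions without E0 replicate 1 (4.34) or 2 (3.56) or E1 replicate 1 (5.09), 2 (5.004), 3 (4.44) or 4 (4.26). For lost regions it was 17.8 with all libraries and fell likewise without E0 replicate 1 (10.7), 2 (11.3), 3 (7.54) or 4 (8.999) or E1 replicate 1 (11.1) or 2 (10.4). Over the other settings the ratio ran from 3.25 to 25.5 for gained regions, highest with lists of equal length, and from 5.89 to 37.1 for lost regions.

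**Figure D3:**
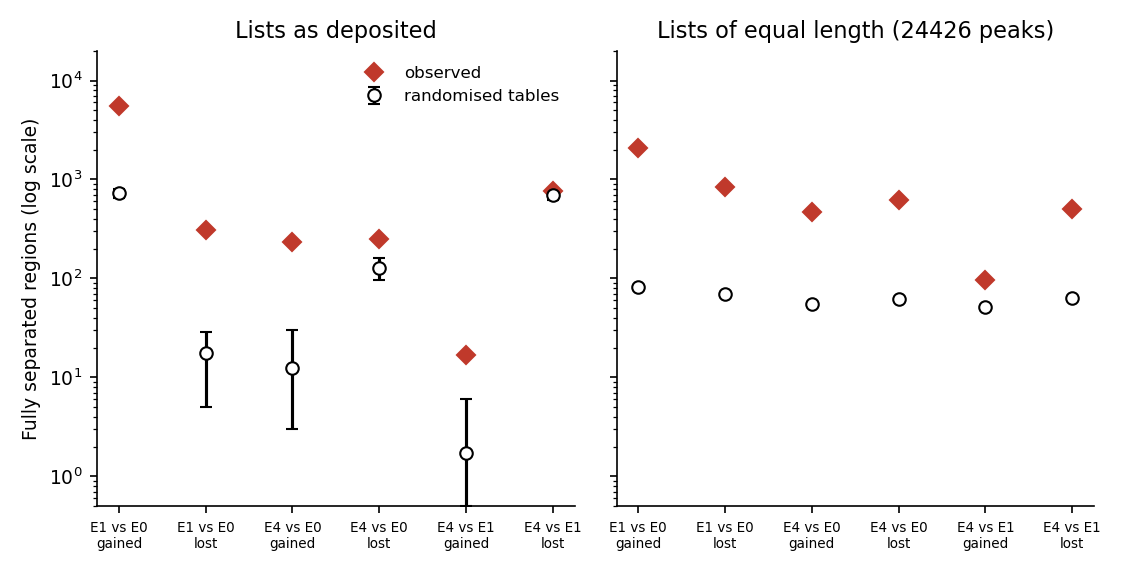
Number of regions fully separated between the groups (log scale) in each comparison and direction, with lists as deposited (left) and with lists of equal length (right); diamonds are observed numbers and circles the mean of randomised tables, with bars at left from the lowest to the highest of 1000 tables (the lowest for E4 vs E1 gained, 0, lies off the axis). At left the E1 vs E0 gained number, 5579, is the highest and exceeds all tables, and at right 2068 regions were gained and 840 lost.

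The comparison of E4 with E0 asks the same of the E4 mice. At E4, 232 regions had a peak in all 4 E4 libraries and in no E0 library, and 248 regions had a peak in all 4 E0 libraries and in no E4 library, out of 11299 regions found in 4 of these 8 libraries. Most regions gained at E4 were also present at E1. Of the 232, 175 (75.4%) had a peak in all 4 E1 libraries, against 30.1% of the other regions found in 4 of the 8 libraries, and 6 had a peak in no E1 library. Of the 248 lost regions, 85 (34.3%) had no peak in any E1 library, against 8.36% of the other regions, and 20 had a peak in all 4. Regions gained at E4 had a median width of 736 bp, against 571 bp for the other regions, and a median percentile of 59.6, against 45.8.

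All 10 named regions gained at E4 had a peak in 4 of 4 E1 libraries. The region with the highest mean percentile lay on chromosome 18 from 31626588 to 31627318, with scores of 139 to 879.5 in the 4 E4 lists. It was followed by chromosome 4 from 17576450 to 17577230, with scores of 139 to 718, and by the E1-gained region on chromosome 18 from 12769458 to 12770505, with scores of 131 to 1068. The next were chromosome 18 from 70550746 to 70551720, with scores of 96.9 to 913, and chromosome 3 from 126622588 to 126624327, with scores of 142 to 464. The regions on chromosome 1 from 40415429 to 40416355 and on chromosome 3 from 120828696 to 120830000, both among the 10 named for E1, were in this list too. The rest lay on chromosome 8 from 95230169 to 95230621, on chromosome 1 from 14474411 to 14475144 and on chromosome 4 from 62943983 to 62944843. With peaks required to cover at least 50% of the region, 1 of these 10 was kept, and with peaks up to 100 bp apart merged 9 were.

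Regions lost at E4 were led by chromosome 10 from 110273639 to 110274230, with a score of 222 ± 82.9 (SD, n = 4) in the E0 lists and a peak in 1 E1 library. On chromosome 15, the region from 43748997 to 43749739 scored 205 ± 31.2 (SD, n = 4) and was present in 3 E1 libraries. The regions on chromosome 6 from 23409054 to 23410706, with a score of 165 ± 36.0 (SD, n = 4), and on chromosome X from 73408355 to 73408876, with a score of 164 ± 46.5 (SD, n = 4), had no peak in any E1 library either. The region on chromosome 13 from 34879358 to 34879954 scored 199 ± 104 (SD, n = 4) and had a peak in 4 of 4 E1 libraries. The other five lay on chromosome 8 from 130003756 to 130004447, chromosome 3 from 66399151 to 66399832 and from 158054419 to 158055171, chromosome 1 from 144318939 to 144319961 and chromosome 15 from 7024936 to 7025670, each present in 1 or 2 E1 libraries. Of these 10, all were kept with lists of equal length and 4 when peaks had to cover at least 50% of the region.

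The number gained at E4 was 18.5 times that of randomised tables, which gave 12.6 ± 3.62 (SD of 1000 tables, 3 to 30), and the number lost was 1.95 times theirs, 127 ± 10.8 (97 to 159), with permutation p = 0.000999 for both. A mixed regrouping, E4 replicate 1 with E0 replicates 1, 2 and 4, also exceeded its tables (3261 regions in both directions, 2076 expected). Cutting lists to 24426 peaks gave 465 gained and 620 lost regions, against 54.7 and 62.5 expected, and requiring peaks to cover at least 50% of a region left 11 gained and 145 lost regions, against 3.41 and 87.3 expected. Leaving out E4 replicate 1, whose list held 104120 peaks against 24426 to 34863 in the other E4 lists, gave 3562 lost regions (1363 expected) and again 232 gained, and other libraries that moved a number by over 1.5 times were E0 replicate 2 (419 gained), E4 replicate 2 (419 gained), E4 replicate 3 (744 gained), E4 replicate 4 (482 gained), E0 replicate 1 (386 lost), E0 replicate 3 (749 lost) and E0 replicate 4 (552 lost). The ratio of the gained number to expectation was 8.50 with lists of 24426 peaks. Over all settings that keep the 8 libraries it ran from 3.23, with 50% of the region covered, to 120. This ratio fell from 18.5 to 6.17, 6.09, 10.1 and 9.40 without E0 replicates 1, 2, 3 and 4 and to 7.46, 7.96 and 7.55 without E4 replicates 2, 3 and 4.

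The lists of regions gained at E1 and at E4 share the E0 libraries, which gives some overlap without any effect. Simulated groups against those controls shared 3.65 gained regions on average (200 tables, at most 9), and independent lists of these lengths would share 7.58, where 175 were observed. For lost regions 85 were shared, against 3.10 in simulated groups (at most 9) and 0.450 for independent lists. Splitting the controls into pairs left the 175 and 85 as they were, because a fully separated region is separated from every pair of controls, and independent lists would then share 14.9 to 24.0 gained and 8.16 to 12.3 lost regions. With lists of equal length 310 of 465 regions gained at E4 (66.7%) were also gained at E1, and 326 of 620 lost regions (52.6%) were lost in both. Simulated groups then shared 4.94 gained (at most 11) and 7.99 lost regions (at most 16), and independent lists would share 14.6 and 7.89. The excess over either expectation is not a measure of a shared effect, since one leaves out the effects and the other the shared controls.

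Regions gained at E1 were found in the E4 libraries to very different extents. Of the 5579, 89.9% had a peak in E4 replicate 1 (95% Wilson interval 89.0 to 90.6), 25.6% in replicate 2 (24.5 to 26.8), 11.9% in replicate 3 (11.04 to 12.7) and 18.6% in replicate 4 (17.6 to 19.6). These intervals cover counting error only. The other regions found in 4 of the 8 E0 and E1 libraries had a peak in 84.3%, 15.9%, 6.56% and 12.6% of cases in the same libraries. All 4 E4 libraries held 175 of the E1-gained regions (3.14%), against 0.615% of the other regions and 1.33% of these when weighted to the same score percentiles. No E4 library held 522 (9.36%), against 13.4%. Regions lost at E1 had a peak in 70.3% of cases in E4 replicate 1 and in 11.9%, 6.45% and 11.3% in E4 replicates 2, 3 and 4, against 86.8%, 19.8%, 8.65% and 15.0% for the other regions. Of the 310, 85 had no peak in any E4 library and 3 had a peak in all 4.

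**Figure D4:**
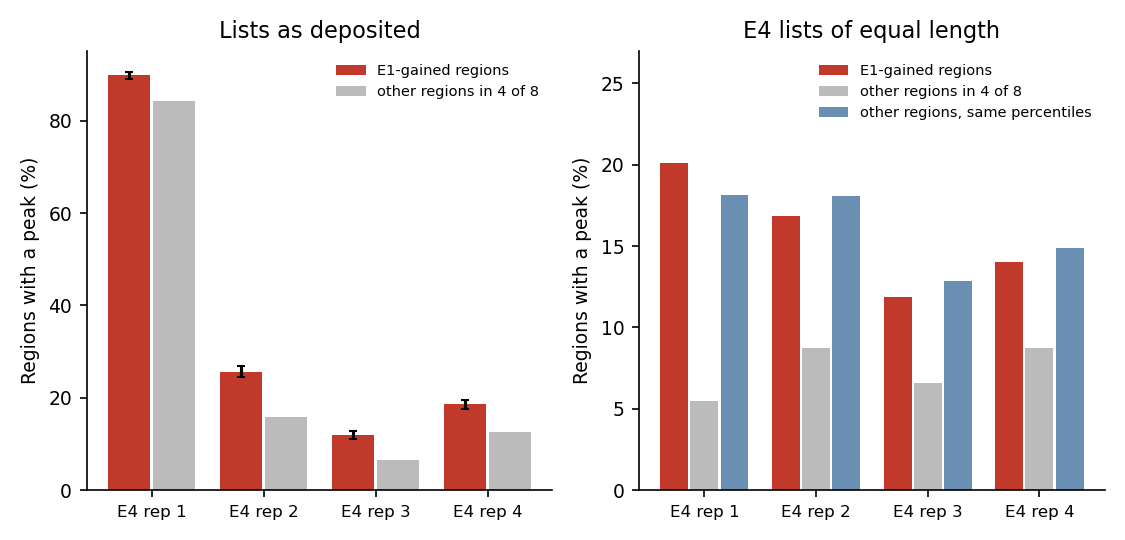
Share of regions with a peak (%) in each E4 replicate, with lists as deposited (left) and E4 lists of equal length (right), for regions gained at E1 (red, with 95% Wilson intervals at left), other regions found in 4 of the 8 E0 and E1 libraries (grey) and, at right, those regions weighted to the same score percentiles (blue). With equal lists the shares of gained regions were 11.9% to 20.1% and the weighted shares 12.8% to 18.1%.

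The comparison of E4 with E1 asks where the E4 mice differ from the E1 mice. In it, 765 regions had a peak in all 4 E1 libraries and in no E4 library, and 17 had a peak in all 4 E4 libraries and in no E1 library, out of 14170 regions found in 4 of these 8 libraries. Of the 765, 522 (68.2%) had no peak in any E0 library, against 32.6% of the other regions, and were thus found at E1 alone, and 20 had a peak in all 4 E0 libraries. Of the 17 gained regions, 6 had no peak in any E0 library and 3 had a peak in all 4. These overlaps with the lists against E0 share the E1 or the E4 libraries, which gives some overlap without any effect. For the 522, simulated groups gave 119 on average (200 tables, at most 151) and independent lists would share 25.0. For the 20, simulated groups gave 34.5 (at most 50), more than observed, and for the 6 and the 3 they gave 0.36 (at most 3) and 0.09 (at most 2). As above, the excess over these values does not measure a shared effect.

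The lost region with the highest mean percentile lay on chromosome 13 from 111188658 to 111193955, 5298 bp wide, with a score of 347 ± 116 (SD, n = 4) in the E1 lists and no peak in E0. The regions on chromosome 10 from 43409436 to 43410127 (271 ± 51.3, SD, n = 4), on chromosome 8 from 36470138 to 36470641 (262 ± 18.0, SD, n = 4) and on chromosome 11 from 18277253 to 18277789 (226 ± 37.3, SD, n = 4) also had no peak in E0 or E4. The same held for chromosome X from 142995299 to 142995734 and chromosome 1 from 133014983 to 133015632. The region on chromosome 2 from 103802476 to 103803074 was present in 4 of 4 E0 libraries. Those on chromosome 18 from 55798399 to 55799549, on chromosome 16 from 86934953 to 86935777 and on chromosome 12 from 93986939 to 93987537 were present in 1 or 2 E0 libraries. Of the gained regions, the first by mean percentile were chromosome 14 from 26064280 to 26065100, chromosome 11 from 35508550 to 35509361, chromosome 6 from 52932943 to 52933705 and chromosome 10 from 20654796 to 20655595, with lowest scores of 68.3 to 82.7 in the E4 lists. The last 3 of these had no peak in E0. The other six, on chromosomes 4, 12, 13, 14, 16 and 17, had a peak in 1 to 4 E0 libraries. With lists of equal length 5 of the 10 gained and 7 of the 10 lost regions were kept, and with peaks required to cover at least 50% of the region 0 and 7 were.

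The number lost from E1 to E4 was 1.10 times that of randomised tables, 694 ± 24.8 (SD of 1000 tables, 616 to 772, permutation p = 0.0020), and the number gained was 9.88 times theirs, 1.72 ± 1.29 (0 to 6, permutation p = 0.000999). Replicates 1 and 2 against 3 and 4 of these groups also exceeded their tables (1021 regions in both directions, 509 expected). With lists of 24426 peaks the split was 96 gained and 503 lost, against 50.9 and 63.2 expected, and with peaks required to cover at least 50% of a region, 2 regions were gained (0.890 expected, permutation p = 0.228) and the lost number fell to 0.900 times expectation. At least 3 of 4 libraries against 0 gave 3082 lost regions against 3229 expected (0.954 times, permutation p = 1). The lost number also fell below expectation without E1 replicate 1 (0.964 times), E1 replicate 3 (0.930), E4 replicate 2 (0.917) or E4 replicate 4 (0.957), and did not pass without E1 replicate 2 (1.03, permutation p = 0.109) or E4 replicate 3 (1.02, permutation p = 0.287). Counts moved by over 1.5 times without E4 replicate 1 (9339 lost, 5881 expected), E1 replicate 2 (1187 lost), E1 replicate 3 (1354 lost), E1 replicate 4 (1715 lost), E4 replicate 2 (64 gained), E4 replicate 3 (64 gained) and E4 replicate 4 (49 gained). The ratio of the gained number to expectation fell to 1.89 with lists of 24426 peaks. It fell to 2.47, 2.60, 4.05 and 4.66 without E1 replicates 1, 2, 3 and 4 and to 4.65, 3.12 and 3.40 without E4 replicates 2, 3 and 4.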

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

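The counts over splits of the libraries in this part were chosen after the result was seen. E4 replicate 1 stood apart from the other E4 libraries in list length, with 104120 peaks on chromosomes 1 to 19 and X against 24426 to 34863, and in covered sequence, with 59.5 Mb against 7.48 to 12.7 Mb. Its gap to the nearest library was 0.869 and 0.899 of the group's range, above Dixon's 95% critical value for 4 samples. Of 12 sets tested (3 groups, 4 measures), chance would flag about 5%, and the 2 measures are not independent. No read count or batch was at hand to separate deeper sequencing from more open chromatin in this mouse, and no biological explanation was tested for it.

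E4 separated from E0 in 480 regions and from E1 in 782, both directions together. Of the 35 splits of the 8 libraries, 6 gave as many for E4 with E0 (highest other 3261, for E4 replicate 1 with E0 replicates 1, 2 and 4) and 6 for E4 with E1 (highest other 4330, for E4 replicate 1 with E1 replicates 1, 2 and 3), so chance cannot be excluded for these counts. The highest other split in each comparison sets the 4 longest lists against the 4 shortest, which not all of the others do, and points to list length as a structure of the samples. Relative to randomised tables that hold it constant, the real E4 and E0 split was the highest of 35 by the ratio (3.38 times expectation, highest other 1.57) but not by the excess in number, where 3 of 35 were as high (338 regions, highest other 1185). For E4 and E1, 7 splits were as high by the ratio (1.12, highest other 2.01) and 5 by the excess (82.4, highest other 1181). The split at 2.01 set replicates 1 and 2 of both groups against replicates 3 and 4. The like split was above expectation for E1 with E0 (1.51 times) and E4 with E0 (1.28 times) too. Within each group replicates 1 and 2 had longer lists and a larger median peak width than replicates 3 and 4. This structure is therefore tied to list length. Randomised tables do not remove it, since the splits of the longest against the shortest lists also exceeded theirs (1.57 times for E4 with E0, 1.37 for E4 with E1). Without E4 replicate 1 the gained regions were 14.5 times expectation, so the excess over tables is seen in the other E4 libraries too. This does not show that the separation from E0 is independent of that list. Leaving it out cannot lower the gained count, and its peaks still helped to set the merged regions. The lost number rose from 248 to 3562 (1363 expected). A response in the E4 mice that is held in few regions and a response missed because 3 of the 4 E4 lists were short both may account for the low gained counts. Which applies stays open without depth. Short lists would raise and not lower the lost counts, which the long list of E4 replicate 1 held down. Without that list the number lost from E1 rose as well, from 765 to 9339, though leaving out a library also relaxes the criterion.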

How the results depend on the processing

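Lists of equal length within each comparison, all alternatives for observed over expected numbers and those for clustering, windows and chromosomes were chosen after the data were seen. The lists hold no reads, so depth limits every call to presence or absence. The promoter, gene list, motif and AP-1 results were not run, for want of an annotation and a genome of the lists' build. Where regions were recounted the criterion or the lists changed; other causes were not tested.

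Peak numbers kept direction and side of the threshold in all 4 other settings per comparison. Leaving out 1 library gave differences of 14414 to 27837 (E1 with E0), -24771 to 1794 (E4 with E0; 1012 without E0 replicate 2) and -45270 to -18705 (E4 with E1). Gained and lost numbers were 2068 and 840 (E1 with E0), 465 and 620 (E4 with E0) and 96 and 503 (E4 with E1) with lists of equal length, and within the comparison 3004 and 1023, 465 and 620, and 96 and 503. Bins of 500 bp gave 3208 and 173, 59 and 97, and 3 and 377. At least 3 of 4 libraries against 0 gave 11902 and 1510, 1181 and 1232, and 145 and 3082. Peaks covering 50% of a region gave 11 and 145 (E4 with E0) and 2 gained (E4 with E1), and peaks above the median score gave 153 gained (E4 with E0). Leaving out 1 library gave 5759 to 8469 and 360 to 950, 232 to 744 and 256 to 3562, and 19 to 64 and 780 to 9339.

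Observed over expected numbers stayed past the threshold in the same direction in all settings for E1 with E0 and E4 with E0, but their size moved. With 1 library left out they were 3.56 to 6.38 gained and 7.54 to 15.0 lost (E1 with E0; 7.65 and 17.8 with all libraries), 6.09 to 14.5 and 1.37 to 2.61 (E4 with E0; 18.5 and 1.95) and 2.47 to 7.54 gained (E4 with E1; 9.88). Over the other settings they were 3.25 to 25.5 and 5.89 to 37.1, 3.23 to 120 and 1.28 to 9.92, and 1.89 to 25.5 gained and 0.900 to 7.96 lost. For E4 with E1, gained was 2.25 (permutation p = 0.228) with 50% covered, and lost was 0.900 with 50% covered, 0.954 with at least 3 of 4, and 0.917 to 1.59 with 1 library left out. The similarity difference passed in all 5 other settings (0.0499 to 0.0660) and ran from 0.0318 to 0.104 with 1 library left out. With lists of equal length the share of regions within 50 kb of another, minus that of draws, kept direction and side of the threshold in 4 of 6 lists. It turned from -0.515 to 3.73 percentage points for regions gained at E4 from E0, and passed at 3.13 for those lost; the cause was not tested. Equal length within the comparison cut the windows past the adjustment for E1-gained regions from 1 to 0 and the chromosomes, in either direction, from 10 to 2.

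Replicate numbers did not pair libraries: deviations of same-numbered libraries correlated at -0.0349 to 0.0668, none over 0.1, and 2, 1 and 0 of 4 libraries were closest to their own number. A replicate block changes only the expectation of the numbers, 5579 and 310, 232 and 248, and 17 and 765. It changed no call (permutation p = 0.0099 each), and it moved observed over expected from 7.65 to 3.74 and 17.8 to 5.89 (E1 with E0, gained and lost). For E4 with E0 it moved them from 18.5 to 16.1 and 1.95 to 2.48, and for E4 with E1 from 9.88 to 6.59 and 1.10 to 1.80.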

Other observations

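In this part the chromosome tests, the counts over splits of the E1 and E0 libraries, the percentiles over sets of 4 libraries, the ratios within replicate pairs and the test of a single rate, both with lists of equal length, and the weighting of presence in all 4 E4 libraries were chosen after the result was seen. Regions gained at E1 were spread unevenly over chromosomes. By Fisher's exact test against the other regions found in 4 of the 8 libraries, with adjustment over 20 chromosomes, they were more frequent on chromosomes 1, 3, 10, 18 and X and less frequent on 7, 9, 11, 17 and 19, and 11 chromosomes had an unadjusted p under 0.05. Chromosome 3 held 8.03% of the gained and 5.69% of the other regions (exact test, adjusted p = 5.97e-07), and chromosome 1 held 9.25% and 7.78% (adjusted p = 0.00677). Chromosome 19 held 1.36% and 2.68% (exact test, adjusted p = 5.97e-07), and chromosome 11 held 3.89% and 5.81% (adjusted p = 1.45e-06). With lists of equal length within the comparison all 10 kept their direction and 2 passed, chromosome 11 (3.53% and 5.36%, exact test, adjusted p = 0.00313) and chromosome 18 (5.23% and 3.87%, adjusted p = 0.0474). Regions lost at E4 were more frequent on chromosome 10 (12.5% against 6.14% of other regions, exact test, adjusted p = 0.00529), and regions lost from E1 to E4 were less frequent on chromosome 19 (0.523% against 2.79%, adjusted p = 2.78e-04). No chromosome passed for regions lost at E1 or gained at E4 from either group, where 2, 2 and 1 had an unadjusted p under 0.05.

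Of the regions that were all or none in each of the 3 groups, 9037 were present in all 12 libraries. The path present at E1 alone held 522 regions, and the path absent at E0 and present at E1 and E4 held 175. The path present at E0 alone held 85 regions, that present at E0 and E1 but not E4 held 20, that present at E4 alone held 6 and that absent at E1 alone held 3.

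The number of regions separated at E1 was reached by the real split alone (1 of 35, 5889 against a highest other of 1349). Relative to randomised tables that hold list length constant, it was again the highest (7.86 times expectation, highest other 1.51). First of 35 is the best rank the design allows, and the count was chosen late. The rank thus speaks against chance without excluding it. For the ratio of gained to lost regions chance stays open, since 10 of 35 splits were as lopsided (18.0, highest other 126) and 6 of 35 with lists of equal length (2.46, highest other 3.88). By the difference the real split was the highest (5269 against 1291, and 1228 against 126). Longer E1 lists alone would give a ratio of 41.8 with lists as deposited, above that observed. With lists of equal length, where no list is longer, 1.16 was expected and 2.46 observed, past the bound of 1.5 set for list length. Because 6 of 35 splits reached 2.46, this does not show that another cause is needed. Weak peaks near the threshold are not the whole cause. The median percentile of gained regions was at least 22.2 points above that of other regions in each E1 library. The same requirement on the 69 other sets of 4 libraries gave 16.3 at most. If replicates 1 and 2 differed from 3 and 4 alike in both groups, this alone could not separate all E1 from all E0 libraries. Within these pairs the ratio was 2.89 and 7.77, against 3.19 and 11.9 from list length. With lists of equal length it was 1.32 and 1.46, under the bound of 1.5. Gained regions still outnumbered lost ones in both pairs (4880 and 3695, 4509 and 3092). The pairs use fewer libraries, a looser criterion, so this bound does not decide the question. A difference between the pairs that is not the same in both groups stays open. A net opening of chromatin in the E1 mice is a hypothesis that stays open, as does a higher share of reads in peaks in the E1 libraries, which peak lists cannot show.

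Equal length of the E4 lists cut the highest share of E1-gained regions in an E4 library from 7.57 to 1.69 times the lowest, so list length is not the whole cause of their uneven presence. The other regions then varied 1.60 times, with their lowest share in E4 replicate 1 (5.48%), where gained regions had their highest (20.1%), and 1.41 times when weighted to the same score percentiles. A single rate for all regions found in 4 of the 8 E0 and E1 libraries met its bound of 1.5 times with lists as deposited (1.07 times the others in E4 replicate 1). That outcome was fixed in advance, because the others already had a peak in 84.3% of cases there. The ratio was 1.61, 1.81 and 1.47 in E4 replicates 2, 3 and 4. With lists of equal length the ratio was at least 1.61 in every E4 library, past the bound of 1.5. Gained regions were the stronger peaks at E1, and a cut by score may favour them. The single rate is therefore not excluded by this excess. Peak strength may account for this excess in single libraries, where the ratio to the weighted regions was 0.925 to 1.11, while all 4 E4 libraries held 3.14% of gained regions against 1.33% of the weighted others, and 1.72% against 0.821% with E4 lists of equal length, a difference that was not tested. The others have peaks in E0 where gained ones have none, so a ratio near 1 does not speak against persistence at E4, and whether gained regions persisted or closed in part stays open for want of depth.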
